A study of Mus musculus with 8 samples.

How the data were processed

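Liver RNA was measured by RNA-seq in 8 libraries from wild-type and MLL4 het-labelled C57 Black mice on chow or HFD, with 2 libraries in each of 4 groups. Per the labels' protocols, total RNA was extracted with an RNeasy kit, and TruSeq libraries were sequenced on an Illumina HiSeq instrument. The labels do not say whether the libraries kept the strand of the RNA, so reads of overlapping or antisense genes cannot be told apart. Groups and library numbers were taken from the titles. The library numbers run from 1 to 8 across the groups, give no batch and tie no library of one group to a library of another.

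The deposited table holds whole-number read counts per gene that are not normalized, as its header and values show, in 22946 rows named by gene symbol. Per the submitters' processing notes, CASAVA, TopHat2, HTSeq, DESeq and the mouse build mm9 were used. Their versions, settings and roles were not given in the sources used here. In 374 rows several symbols are joined, and such a row cannot be divided between its genes. Counts of near-identical gene copies that stand in separate rows are uncertain too, because the treatment of reads with several matches was not given. The merged row of major urinary protein genes took between 7.42% and 13.6% of the counts of a library. In 5826 rows all libraries had 0 counts. The 13 protein genes of the mitochondrial genome and a few members of the fixed gene lists were not analysed here. Symbols were placed in a table of mouse genes of assembly GRCm38.p6, which is not the build of the counts and served only for current names and for which genes neighbour each other, and 12484 of the 12593 tested rows could be placed.

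Counts were analysed with edgeR 4.0.16 in R 4.3.3. Rows were kept by the edgeR function filterByExpr, which left 12593, and library sizes were scaled with TMM factors. A quasi-likelihood model of 4 group means was fitted to all 8 libraries, so that groups of 2 share an estimate of the spread, with 4 residual degrees of freedom and 4.77 prior degrees of freedom. The common biological coefficient of variation was 11.2%, and within groups it was 7.59% in wild-type chow, 8.70% in wild-type HFD, 13.8% in het-labelled chow and 13.6% in het-labelled HFD libraries. Tests were 2-sided, p-values were adjusted over all tested rows by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The comparisons were HFD against chow in each genotype, het-labelled against wild-type on each diet, and the interaction of genotype and diet. Each SE was calculated back from the log2 change and the statistic of its test, and each 95% interval was built from that SE. Both are therefore approximate. CPM values use the TMM factors.

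The comparisons, their tests, 35 gene lists, the alternatives and the rule for named genes were chosen before the data were examined. In each comparison the rule names the 10 called genes with the largest rise and the 10 with the largest fall, among genes with a mean of at least 1 CPM whose 2 groups do not overlap. With fewer than 5 called genes it names the 10 with the smallest p instead, as genes that did not pass. From each list described it takes up to 4 called members with the smallest adjusted p, or else up to 3 members as values, and a fixed panel of genes of interest is always included. The texts name part of these genes. Of the 35 lists, 27 had at least 5 tested members and were not kept for checks alone, and these were tested with camera (limma 3.58.1). It asks whether the test statistics of the genes of a list differ on average from those of the other genes. Camera was run with a preset correlation of 0.01 between genes and again with a correlation estimated from the data, and p-values were adjusted over the 27 lists. The rotation test fry asks whether the genes of a list move, on balance, one way, or, in its mixed form, whether they change in either direction, without setting them against other genes. Members of a list were also adjusted over the list alone.

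Genes called in wild-type and not in het-labelled livers were set against counts simulated 20 times with the same diet effect in both genotypes. A second comparison selected genes on 1 pair of libraries (log2 ratio of at least 1, after adding 1 to CPM) and measured them in the remaining pair and in the other genotype. Comparisons that share libraries were set against values simulated with no effect. The procedure was tested on simulated counts, drawn gene by gene with a single dispersion per gene, in which known genes were changed by known folds. In those, the share of 2-fold and 4-fold changes recovered was 79% and 89% for the diet in wild-type livers, 77% and 97% for the diet in het-labelled livers, 74% and 96% for the genotype on HFD, 72% and 95% for the genotype on chow, and 45% and 88% for the interaction. The simulation with the same diet effect in both genotypes, from the same dispersions, called more genes than observed (938 against 578 in wild-type livers). The shares recovered may therefore overstate what these data allow. Alternatives were size factors by relative log expression, upper-quartile factors, no filter, a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, a fit to the compared groups alone, an adjusted p under 0.10 and leaving out each library in turn. Leaving out libraries for the count of genes called in wild-type alone, and simulating with a dispersion per genotype, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.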

Results

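RNA-seq read counts per gene were analysed from total RNA of livers of C57 Black mice fed either chow or a high fat diet (HFD) for 8 weeks from the age of 8 weeks. The mice were wild-type or labelled heterozygous for MLL4, a histone methyltransferase that marks enhancers and is encoded by Kmt2d. Each of the 4 groups held 2 libraries. Total counts were 15509216 and 17330137 in wild-type chow libraries 1 and 2, 17054887 and 18813837 in wild-type HFD libraries 5 and 6, 14184486 and 14460892 in het-labelled chow libraries 3 and 4, and 18928676 and 14142884 in het-labelled HFD libraries 7 and 8. Levels are given as CPM, the counts of a gene per 1e+06 counts of its library. A count of 3 corresponded to between 0.158 and 0.212 CPM in these libraries. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical. The 2 libraries of each group differed by more than sampling noise (chi-square per degree of freedom 15.4 to 16.8), and each was counted as a sample. In a principal component analysis, component 1 held 37.5% of the variance and separated chow from HFD, and component 2 held 22.2% and separated wild-type from het-labelled libraries. Component 3 held 14.2%, with het-labelled HFD library 8 at 28.6 and het-labelled chow library 3 at -20.6. Values below are mean ± SD of CPM (n = 2 per group), and log2 changes are given ± SE.

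The gene named in the genotype label was examined first. Kmt2d, listed under its older symbol Mll2, stood at 61.2 and 69.6 CPM in the wild-type chow libraries, 63.3 and 64.7 in wild-type HFD, 59.95 and 72.1 in het-labelled chow, and 62.8 and 75.4 in het-labelled HFD. The log2 difference between het-labelled and wild-type livers was 0.01 ± 0.13 on chow (95% interval -0.27 to 0.30, edgeR adjusted p = 0.975) and 0.11 ± 0.12 on HFD (95% interval -0.17 to 0.39, edgeR adjusted p = 0.760). Its RNA was therefore not lower in the libraries labelled MLL4 het. The labels do not give the allele, and a count over the whole gene does not show a change that leaves the amount of RNA as it was, so these libraries are called het-labelled throughout. Of 16 tested genes in the fixed list of H3K4 methyltransferase complexes, to which Kmt2d belongs, 0 were called in any of the 4 pairwise comparisons. Adjusted over the list alone, 1 was higher in het-labelled livers on HFD and 0 on chow. The list's median log2 difference was 0.12 on HFD (camera adjusted p = 0.0245, and adjusted p = 0.262 with an estimated correlation) and 0.14 on chow (camera adjusted p = 0.0235, and adjusted p = 0.287 with an estimated correlation).

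The comparison named first in the series design asks which genes the high fat diet alters in wild-type liver. In wild-type livers on HFD, genes of fatty acid synthesis and of lipid droplets were higher than on chow. Fasn, which encodes fatty acid synthase, rose from 276 ± 84.1 to 1532 ± 33.4 CPM (log2 fold change 2.47 ± 0.30, edgeR adjusted p = 0.00374). Pklr, the liver pyruvate kinase, rose from 93.1 ± 8.02 to 449 ± 38.2 CPM (log2 fold change 2.27 ± 0.14, edgeR adjusted p = 0.00017). Pnpla3, a lipid droplet protein of the patatin-like phospholipase family, rose from 0.563 ± 0.351 to 32.2 ± 19.9 CPM (log2 fold change 5.79 ± 0.59, edgeR adjusted p = 0.00204). Of 26 tested genes of de novo lipogenesis, 13 rose and 0 fell (18 and 1 adjusted over the list alone). With camera the list had adjusted p = 8.04e-24, and adjusted p = 0.116 with an estimated correlation. Scd1, the main hepatic stearoyl-CoA desaturase, rose from 6089 ± 2781 to 29294 ± 5795 CPM (log2 fold change 2.27 ± 0.37, edgeR adjusted p = 0.0125). Srebf1, a transcription factor of lipogenic genes, rose from 161 ± 66.3 to 716 ± 234 CPM (log2 fold change 2.15 ± 0.38, edgeR adjusted p = 0.0175).

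Lipid-droplet genes rose as well. Of 32 lipid-droplet genes known as targets of PPARG, 11 rose and 0 fell (20 and 1 adjusted over the list alone). Its camera test gave adjusted p = 6.90e-19, and adjusted p = 0.0849 with an estimated correlation. Mgll, monoacylglycerol lipase, rose from 95.1 ± 0.172 to 276 ± 42.1 CPM (log2 fold change 1.54 ± 0.12, edgeR adjusted p = 0.000628). Cidec, which enlarges lipid droplets, rose from 2.999 ± 0.678 to 21.2 ± 10.7 CPM (log2 fold change 2.81 ± 0.41, edgeR adjusted p = 0.00833). Plin2, a lipid droplet coat protein, rose from 426 ± 67.97 to 719 ± 61.5 CPM (log2 fold change 0.75 ± 0.12, edgeR adjusted p = 0.0125). Mogat1, an enzyme of triglyceride synthesis, rose from 0.578 ± 0.162 to 3.86 ± 2.05 CPM (log2 fold change 2.73 ± 0.45, edgeR adjusted p = 0.0137). Cidea, a relative of Cidec, had 0 and 0 counts on chow and 145 and 22 on HFD, and did not pass (edgeR adjusted p = 0.0538). Apoa4, an apolipoprotein of triglyceride-rich particles, rose from 33.1 ± 2.32 to 941 ± 308 CPM (log2 fold change 4.83 ± 0.39, edgeR adjusted p = 0.000628). Mfsd2a, a transporter of lysophosphatidylcholine, rose from 13.1 ± 0.853 to 136 ± 7.80 CPM (log2 fold change 3.38 ± 0.12, edgeR adjusted p = 9.30e-06). The list's median was 0.59, the same with Cidea at the lower bound set by 3 counts per library, and 0.53 without Cidea. Pparg itself stood at 11.2 ± 0.153 CPM on chow and 14.7 ± 2.98 on HFD and did not pass (edgeR adjusted p = 0.217). The calls of Scd1 (without library 1 or 5), Srebf1 (without 1 or 6), Cidec (without 1 or 2), Plin2 (without 2 or 5) and Mogat1 (without 1, 2 or 5) ended, with edgeR adjusted p up to 0.147. The lipogenesis count fell to 5 without library 1, 7 without library 5 and 8 without library 6, and the lipid-droplet count fell to 4 without library 1 or library 2.

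Genes of cholesterol synthesis and of xenobiotic metabolism were lower in wild-type livers on HFD. Sqle, squalene epoxidase, fell from 73.4 ± 8.53 to 6.86 ± 4.67 CPM (log2 fold change -3.43 ± 0.40, edgeR adjusted p = 0.00361). Idi1, an isomerase of the isoprenoid pathway, fell from 298 ± 23.95 to 38.6 ± 18.2 CPM (log2 fold change -2.95 ± 0.40, edgeR adjusted p = 0.00678). Of 26 tested genes of cholesterol synthesis, 0 rose and 16 fell (1 and 19 adjusted over the list alone). The camera adjusted p was 1.81e-26, and adjusted p = 0.171 with an estimated correlation. Cyp1a2, a hepatic cytochrome P450, fell from 797 ± 27.2 to 300.1 ± 1.53 CPM (log2 fold change -1.41 ± 0.09, edgeR adjusted p = 0.00025). Cyp2b10, a cytochrome P450 induced by drugs, fell from 23.3 ± 0.464 to 3.001 ± 0.163 CPM (log2 fold change -2.95 ± 0.16, edgeR adjusted p = 0.000123). Gsta4, a glutathione transferase, fell from 61.9 ± 1.80 to 23.8 ± 1.95 CPM (log2 fold change -1.38 ± 0.10, edgeR adjusted p = 0.000261). Of 39 genes of xenobiotic metabolism, 0 rose and 20 fell (2 and 29 adjusted over the list alone). Tested with camera, the list had adjusted p = 5.47e-42, and adjusted p = 0.0479 with an estimated correlation. Of 28 acute phase genes, 0 rose and 9 fell (0 and 15 adjusted over the list alone). Camera gave this list an adjusted p of 3.53e-12, and adjusted p = 0.0489 with an estimated correlation. Among its called genes Saa3, a serum amyloid A, fell from 8.05 ± 0.730 to 1.78 ± 0.505 CPM (log2 fold change -2.18 ± 0.21, edgeR adjusted p = 0.00181). Cyp7b1, an oxysterol hydroxylase of the alternative bile acid pathway, fell from 387 ± 103 to 135 ± 17.2 CPM (log2 fold change -1.52 ± 0.19, edgeR adjusted p = 0.00483). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 53.2 ± 6.18 to 27.6 ± 3.20 CPM (log2 fold change -0.95 ± 0.20, edgeR adjusted p = 0.0328). Of 28 genes of bile acid synthesis and transport, 1 rose and 6 fell (5 and 9 adjusted over the list alone), and the list did not pass. The Cyp7a1 call ended without any 1 of libraries 1, 2, 5 and 6, with edgeR adjusted p up to 0.195. The count of lower cholesterol genes was 7, 3 and 4 without libraries 1, 2 and 6, that of xenobiotic genes 12 without library 1 or 5, that of acute phase genes 3, 4 and 5 without libraries 1, 2 and 6, and that of bile acid genes 1, 1, 2 and 1 without libraries 1, 2, 5 and 6. The number of risen bile acid genes was 0 without library 1 or 2, 3 without library 3 or 4 and 2 without library 5, 7 or 8.

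Sugar metabolism, fatty-acid oxidation and other groups also differed between the diets in wild-type livers. Khk, ketohexokinase, rose from 267 ± 26.5 to 572 ± 73.8 CPM (log2 fold change 1.10 ± 0.11, edgeR adjusted p = 0.00190). Of 26 genes of gluconeogenesis and glycogen, 8 rose and 1 fell (13 and 2 adjusted over the list alone). With camera the list had adjusted p = 6.10e-05, and adjusted p = 0.277 with an estimated correlation. Of 43 genes of PPARA fatty-acid oxidation, 9 rose and 0 fell (14 and 0 adjusted over the list alone). Its camera test gave adjusted p = 4.40e-07, and adjusted p = 0.372 with an estimated correlation. Acaa1b, a peroxisomal thiolase, rose from 1214 ± 214 to 2527 ± 77.5 CPM (log2 fold change 1.06 ± 0.15, edgeR adjusted p = 0.00796). Bhlhe40, a repressor within the circadian clock, rose from 58.5 ± 20.4 to 193 ± 21.4 CPM (log2 fold change 1.72 ± 0.24, edgeR adjusted p = 0.00751). Of 22 clock genes, 3 rose and 0 fell (6 and 0 adjusted over the list alone). The camera adjusted p was 6.10e-05, and adjusted p = 0.259 with an estimated correlation. Asns, asparagine synthetase, fell from 6.63 ± 1.28 to 0.480 ± 0.137 CPM (log2 fold change -3.78 ± 0.29, edgeR adjusted p = 0.000476). It was the only called gene among 26 of the unfolded protein response, of which 6 and 5 others rose when library 3 or 4 was left out. Rian and the merged row holding Meg3, noncoding RNAs of the same imprinted cluster, fell by 4.10 and 3.61 on the log2 scale (edgeR adjusted p = 0.00364 and 0.00654). Of 29 hepatocyte genes, 0 rose and 6 fell (1 and 7 adjusted over the list alone). Tested with camera, the list had adjusted p = 1.28e-05, and adjusted p = 0.347 with an estimated correlation. C3, complement component 3, fell from 6162 ± 961 to 2805 ± 212 CPM (log2 fold change -1.14 ± 0.13, edgeR adjusted p = 0.00299). Markers of blood moved with the diet in wild-type libraries, where the merged rows of alpha and beta haemoglobin rose from 122 ± 32.4 to 421 ± 88.01 CPM (log2 fold change 1.79 ± 0.20, edgeR adjusted p = 0.00261) and from 47.7 ± 12.4 to 179 ± 36.6 CPM (log2 fold change 1.91 ± 0.19, edgeR adjusted p = 0.00181). The list of PPARA genes held 0, 2, 1 and 5 risen genes without libraries 1, 2, 5 and 6, and the call of Acaa1b ended without library 1 (edgeR adjusted p = 0.0813). Risen gluconeogenesis genes numbered 2, 2, 4 and 3 without those libraries, fallen ones 0, and fallen hepatocyte genes 1, 1, 1 and 3. Clock genes numbered 1 without library 1 or 2 and 5 without library 6, 7 or 8, and the call of the Meg3 row ended without library 6 (edgeR adjusted p = 0.0571).

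In total, 578 of 12593 tested genes differed between diets in wild-type livers, 299 higher and 279 lower on HFD (edgeR quasi-likelihood test, adjusted p under 0.05). This count was 98, 130, 199 and 182 without libraries 1, 2, 5 and 6, and 896 and 887 without het-labelled chow libraries 3 and 4, which enter the estimate of the spread. Camera passed 15 of 27 lists, of which 2, xenobiotic metabolism and acute phase, passed with an estimated correlation.

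In het-labelled livers, the same question was asked of the diet response. Genes of lipogenesis rose and genes of cholesterol synthesis and xenobiotic metabolism fell here too. Fasn rose from 238 ± 81.6 to 973 ± 299 CPM (log2 fold change 2.03 ± 0.29, edgeR adjusted p = 0.0131). Pklr rose from 85.3 ± 15.02 to 358 ± 24.2 CPM (log2 fold change 2.07 ± 0.14, edgeR adjusted p = 0.000285). Thrsp, a lipogenic nuclear protein, rose from 42.8 ± 17.1 to 346 ± 24.7 CPM (log2 fold change 3.01 ± 0.42, edgeR adjusted p = 0.0120). Of 26 lipogenesis genes, 10 rose and 0 fell (14 and 1 adjusted over the list alone). Camera gave this list an adjusted p of 2.43e-16, and adjusted p = 0.142 with an estimated correlation. Of 32 lipid-droplet genes, 6 rose and 0 fell (9 and 1 adjusted over the list alone). With camera the list had adjusted p = 2.36e-08, and adjusted p = 0.142 with an estimated correlation. The list's median was 0.36, 0.335 without Cidea and 0.223 without library 7. Apoa4 rose from 71.3 ± 40.05 to 449 ± 31.1 CPM (log2 fold change 2.66 ± 0.36, edgeR adjusted p = 0.00921). Dgat2, which makes triglyceride, rose from 256 ± 6.72 to 438 ± 53.6 CPM (log2 fold change 0.78 ± 0.10, edgeR adjusted p = 0.00828). Cidec stood at 1.72 ± 0.834 CPM on chow and 2.71 ± 1.02 on HFD and did not pass (edgeR adjusted p = 0.582), and Plin2 stood at 325 ± 14.02 and 424 ± 26.3 and did not pass (edgeR adjusted p = 0.137). Of 26 genes of cholesterol synthesis, 0 rose and 11 fell (0 and 18 adjusted over the list alone). Its camera test gave adjusted p = 1.95e-21, and adjusted p = 0.142 with an estimated correlation. Sqle fell from 58.4 ± 2.05 to 3.86 ± 2.19 CPM (log2 fold change -3.97 ± 0.44, edgeR adjusted p = 0.00546). Hmgcs1, HMG-CoA synthase, fell from 358 ± 65.2 to 118 ± 17.3 CPM (log2 fold change -1.60 ± 0.20, edgeR adjusted p = 0.00758). Of 39 xenobiotic genes, 0 rose and 14 fell (0 and 26 adjusted over the list alone). The camera adjusted p was 7.54e-35, and adjusted p = 0.0483 with an estimated correlation. Cyp2b10 fell from 22.6 ± 3.55 to 0.437 ± 0.0865 CPM (log2 fold change -5.69 ± 0.22, edgeR adjusted p = 7.50e-06). Slc39a4, a zinc importer, fell from 32.5 ± 5.21 to 2.26 ± 0.375 CPM (log2 fold change -3.82 ± 0.17, edgeR adjusted p = 2.09e-05). Of 26 genes of gluconeogenesis and glycogen, 7 rose and 0 fell (10 and 0 adjusted over the list alone). Tested with camera, the list had adjusted p = 1.03e-06, and adjusted p = 0.142 with an estimated correlation. Gys2, liver glycogen synthase, rose from 83.6 ± 6.58 to 135 ± 1.94 CPM (log2 fold change 0.69 ± 0.09, edgeR adjusted p = 0.00828). The lipogenesis count was 4 and 5 without libraries 4 and 7, and the gluconeogenesis count 4, 4 and 3 without libraries 3, 4 and 7. The cholesterol count was 6, 5, 7, 4 and 4 without libraries 1, 2, 3, 4 and 7, and the xenobiotic count 9 without any 1 of libraries 1, 2 and 3.

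Clock genes, immediate early genes and Kupffer cell markers moved with the diet in het-labelled livers. Per2, a core clock repressor, rose from 7.59 ± 3.70 to 32.9 ± 6.89 CPM (log2 fold change 2.12 ± 0.27, edgeR adjusted p = 0.00828). Tef, a clock-controlled transcription factor, rose from 25.3 ± 2.95 to 101 ± 21.8 CPM (log2 fold change 1.997 ± 0.23, edgeR adjusted p = 0.00552). Per3 rose from 1.40 ± 0.531 to 14.6 ± 2.09 CPM (log2 fold change 3.39 ± 0.48, edgeR adjusted p = 0.0121). Of 22 clock genes, 10 rose and 0 fell (16 and 3 adjusted over the list alone). Camera gave this list an adjusted p of 1.48e-14, and adjusted p = 0.0857 with an estimated correlation. Of 23 immediate early genes, 4 rose and 1 fell (12 and 1 adjusted over the list alone). With camera the list had adjusted p = 1.90e-08, and adjusted p = 0.142 with an estimated correlation. Among them Fos stood at 0.850 and 3.88 CPM in the chow libraries and 12.02 and 80.4 in HFD libraries 7 and 8. Hspa1a and Hspa1b, heat shock genes so similar that their reads are hard to divide, also differed between these libraries, with 94.4 and 188 CPM in library 8 against 18.5 and 36.3 in library 7. Of 19 markers of Kupffer cells and macrophages, 0 rose and 10 fell (0 and 19 adjusted over the list alone). Its camera test gave adjusted p = 2.60e-21, and adjusted p = 0.142 with an estimated correlation. Lyz2, lysozyme 2, fell from 68.7 ± 2.86 to 24.6 ± 12.3 CPM (log2 fold change -1.47 ± 0.27, edgeR adjusted p = 0.0269). Clec4f, a Kupffer cell lectin, fell from 117 ± 9.79 to 62.6 ± 17.4 CPM (log2 fold change -0.89 ± 0.17, edgeR adjusted p = 0.0287). Stellate markers had a median of -0.20 (camera adjusted p = 0.0241, and adjusted p = 0.432 with an estimated correlation), a call that ended without library 3 or 8, and lymphocyte markers, which did not pass, one of -0.41. Of 28 acute phase genes, 0 rose and 8 fell (0 and 12 adjusted over the list alone). The camera adjusted p was 1.00e-09, and adjusted p = 0.0712 with an estimated correlation. Of 25 inflammation genes, 0 rose and 1 fell (0 and 6 adjusted over the list alone). Tested with camera, the list had adjusted p = 4.25e-06, and adjusted p = 0.142 with an estimated correlation. Cyp4a14, an omega-hydroxylase of fatty acids, fell from 437 ± 406 to 41.8 ± 7.94 CPM (log2 fold change -3.39 ± 0.61, edgeR adjusted p = 0.0269). Its chow libraries 3 and 4 stood at 149 and 724 CPM. The fatty-acid oxidation list as a whole did not pass. The number of fallen Kupffer markers was 0 without any 1 of libraries 1, 2 and 3, 5 without library 5 or 6, 4 without library 4 and 3 without library 8. Risen immediate early genes numbered 0 without library 4, 1 without library 1, 2, 3 or 8, 2 without library 5 or 6 and 6 without library 7, and their median of 0.87 fell to 0.37 without library 8. The fallen immediate early gene was called without library 5 or 6 and not without the others. Clock genes numbered 6 without library 1 or 2 and 5 without library 3 or 4, and fallen acute phase genes 2, 2, 4, 3, 3 and 2 without libraries 1, 2, 3, 4, 7 and 8. The calls of Per3 (without library 4), Lyz2 and Clec4f (without library 1, 2, 3 or 4) and Cyp4a14 (without library 1, 2, 7 or 8) ended with edgeR adjusted p up to 0.115, and that of Fos ended without any 1 library other than 7, with a mean CPM of at least 5 and with limma-voom (adjusted p up to 0.207).

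Of the 12593 genes, 380 differed between diets in het-labelled livers, 193 higher and 187 lower on HFD (edgeR, adjusted p under 0.05). Without libraries 1, 2, 4 and 7 the count was 146, 144, 226 and 198, and without library 3 it was 241. A fit to the het-labelled libraries alone called 105 genes, against 1351 in a fit to the wild-type libraries alone. Camera passed 14 of 27 lists, of which 1, xenobiotic metabolism, passed with an estimated correlation. In the comparison of both diet responses, 111 genes rose in wild-type and in het-labelled livers (4.58 for independent lists) and 101 fell in both (4.14), while 0 went opposite ways. Across genes, which are not independent replicates, the log2 fold changes of the 2 genotypes had r = 0.586 and a covariance of 0.0704, with no library in common.

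**Figure D1:**
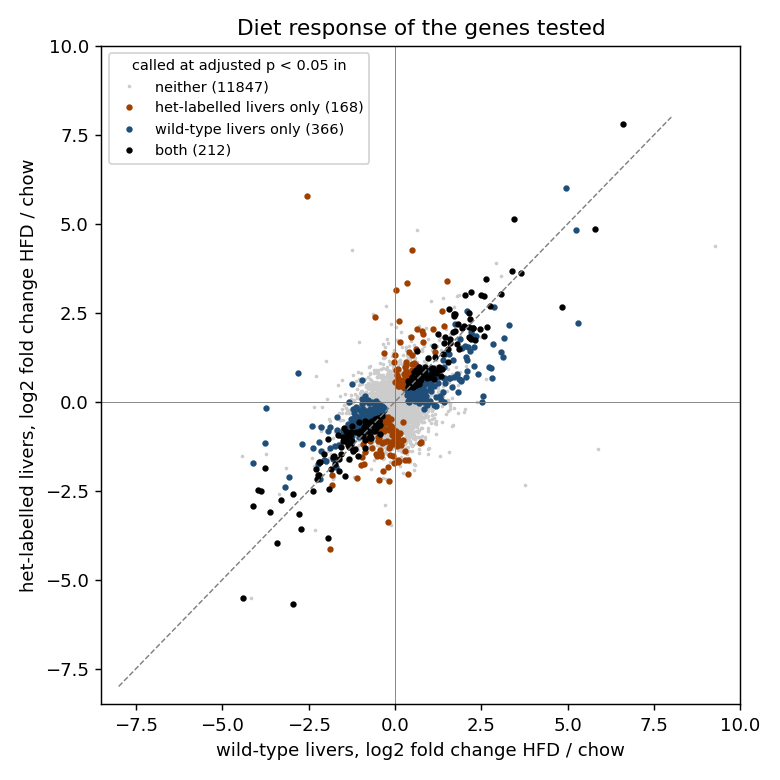
Log2 fold change from chow to HFD of each tested gene in wild-type livers (horizontal axis) and in het-labelled livers (vertical axis), with a dashed line of equal change, coloured by whether edgeR called it in both genotypes (212 genes), in wild-type alone (366), in het-labelled alone (168) or in neither. A call in 1 genotype alone is no tested difference between them, and genes without reads in a group lie where the fit places them and have no measured fold.

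**Figure D2:**
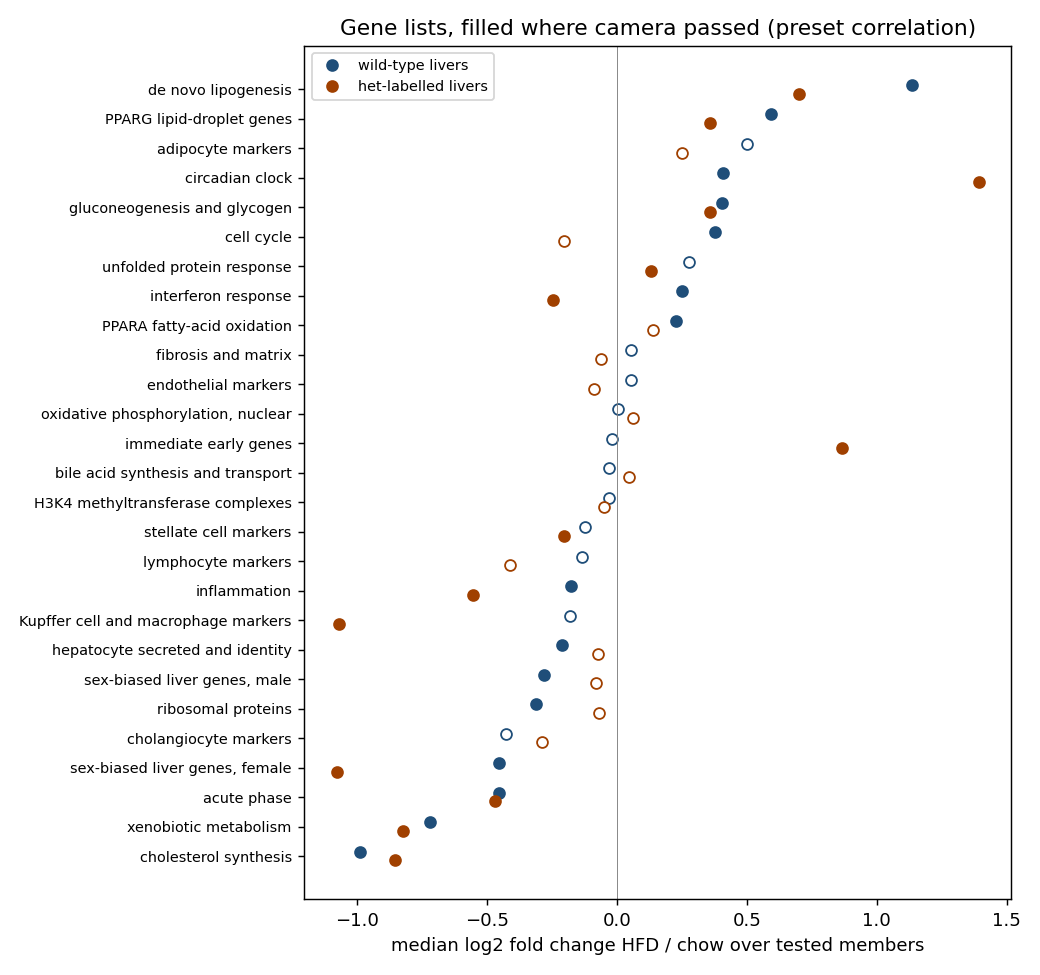
Median log2 fold change from chow to HFD over the tested members of the 27 tested gene lists, in wild-type and in het-labelled livers, with filled points where camera passed with its preset correlation. Most of these calls did not pass with an estimated correlation, and medians such as 1.14 and 0.70 for de novo lipogenesis and -0.18 and -1.07 for Kupffer markers are compared by the interaction of genotype and diet, at -0.332 for de novo lipogenesis (camera adjusted p = 0.0112, and adjusted p = 0.627 with an estimated correlation) and -0.873 for Kupffer markers (camera adjusted p = 4.28e-15, and adjusted p = 0.317 with an estimated correlation).

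On HFD, het-labelled livers were compared with wild-type livers to find genes that differ between the genotype labels on this diet. Genes of lipid droplets were lower in het-labelled livers. Cidec stood at 21.2 ± 10.7 CPM in wild-type and 2.71 ± 1.02 in het-labelled livers (log2 difference -2.93 ± 0.41, edgeR adjusted p = 0.0317). Fitm1, a protein that promotes fat storage in droplets, stood at 63.1 ± 4.43 CPM in wild-type and 14.5 ± 7.81 in het-labelled livers (log2 difference -2.10 ± 0.29, edgeR adjusted p = 0.0304). Plin4 stood at 22.7 ± 8.47 CPM in wild-type and 7.45 ± 0.0809 in het-labelled livers (log2 difference -1.60 ± 0.25, edgeR adjusted p = 0.0378). Mogat1 stood at 3.86 ± 2.05 CPM in wild-type and 0.482 ± 0.0776 in het-labelled livers (log2 difference -2.96 ± 0.47, edgeR adjusted p = 0.0443). Of 32 lipid-droplet genes, 0 were higher and 5 lower (1 and 16 adjusted over the list alone). Camera gave this list an adjusted p of 2.37e-17, and adjusted p = 0.195 with an estimated correlation. Its median log2 difference was -0.48. Plin2 stood at 719 ± 61.5 CPM in wild-type and 424 ± 26.3 in het-labelled livers (log2 difference -0.76 ± 0.12, edgeR adjusted p = 0.0455). Cd36, a fatty acid transporter, stood at 117 ± 28.1 and 28.02 ± 19.3 CPM and did not pass (edgeR adjusted p = 0.0653), and Cidea had 145 and 22 counts in wild-type and 4 and 1 in het-labelled libraries (edgeR adjusted p = 0.160). Fasn, Scd1 and Srebf1 did not pass, with log2 differences of -0.65 ± 0.28, -0.48 ± 0.35 and 0.04 ± 0.36. Of 26 lipogenesis genes, 0 were higher and 0 lower (0 and 4 adjusted over the list alone). With camera the list had adjusted p = 3.16e-05, and adjusted p = 0.488 with an estimated correlation. Without library 5, 1 lipogenesis gene was lower. Of 43 genes of PPARA fatty-acid oxidation, 0 were higher and 1 lower (0 and 20 adjusted over the list alone). Its camera test gave adjusted p = 2.12e-17, and adjusted p = 0.262 with an estimated correlation. The called gene was Ehhadh, the peroxisomal bifunctional enzyme, at 450.0 ± 26.5 CPM in wild-type and 301 ± 12.4 in het-labelled livers (log2 difference -0.58 ± 0.09, edgeR adjusted p = 0.0473). Each of these 6 calls ended without library 1 or 2, and also without 5 or 8 (Cidec), 5 or 6 (Fitm1), 6, 7 or 8 (Plin4), 5, 7 or 8 (Mogat1) and 5, 6, 7 or 8 (Plin2, Ehhadh), with edgeR adjusted p up to 0.242. Those of Cidec, Plin4 and Mogat1 ended with limma-voom, those of Plin4, Plin2 and Ehhadh with a mean CPM of at least 5, and those of Plin2 and Ehhadh with upper-quartile scaling. The count of lower lipid-droplet genes was 0 without library 1 or 2, 1 without library 5 or 8 and 3 without library 6, and that of lower PPARA genes was 0 without library 1, 2, 5, 6 or 8, 6 without library 3 or 4 and 5 without library 7.

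**Figure D3:**
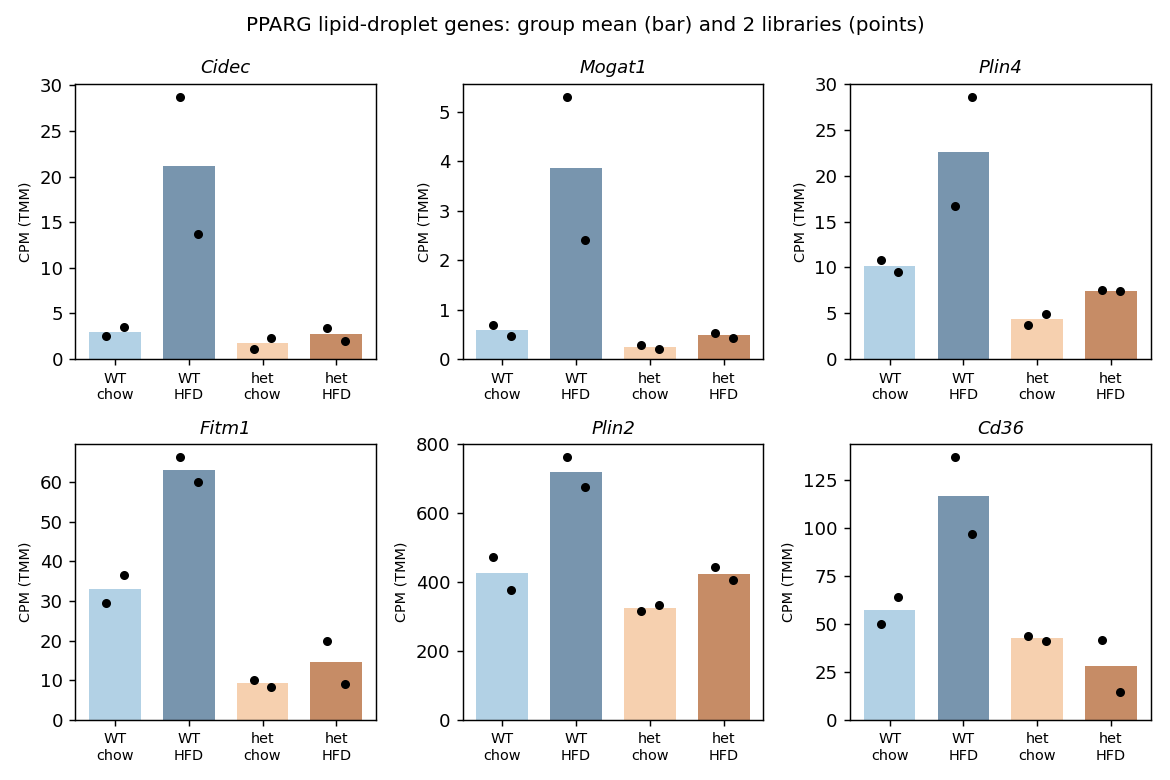
CPM (linear axes from 0, scaled with TMM factors) of Cidec, Mogat1, Plin4, Fitm1, Plin2 and Cd36 in the 4 groups, with bars for group means and points for the 2 libraries of each group. Cidec stood at 28.7 and 13.7 CPM in the wild-type HFD libraries and at 3.43 and 1.99 in the het-labelled HFD libraries.

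Genes outside lipid metabolism also differed on HFD. Slc39a4 stood at 15.9 ± 0.804 CPM in wild-type and 2.26 ± 0.375 in het-labelled livers (log2 difference -2.79 ± 0.18, edgeR adjusted p = 0.000564). Aqp4, a water channel, stood at 14.7 ± 0.282 CPM in wild-type and 1.81 ± 0.0556 in het-labelled livers (log2 difference -3.02 ± 0.19, edgeR adjusted p = 0.000564). Cyp2b10 stood at 3.001 ± 0.163 CPM in wild-type and 0.437 ± 0.0865 in het-labelled livers (log2 difference -2.79 ± 0.27, edgeR adjusted p = 0.00636). Alas2, the erythroid 5-aminolevulinate synthase, stood at 141 ± 1.17 CPM in wild-type and 65.6 ± 6.17 in het-labelled livers (log2 difference -1.10 ± 0.10, edgeR adjusted p = 0.00411). Mettl7a3 was read in 1 and 2 counts in wild-type and 176 and 120 in het-labelled libraries (edgeR adjusted p = 0.00275), and the merged row of its relative Mettl7a2 stood at 8.13 ± 0.906 CPM in wild-type and 22.1 ± 2.12 in het-labelled livers (log2 difference 1.44 ± 0.13, edgeR adjusted p = 0.00466). Reads of these near-identical copies can be divided wrongly between them, so their levels are uncertain. These 6 calls stood without each library in turn and under the other alternatives run for each gene. Mettl7a3 lay below the filter at a mean of 5 CPM and was not tested with it. The fit to the compared groups alone was not checked gene by gene. Cyp7a1 was higher, at 27.6 ± 3.20 CPM in wild-type and 91.7 ± 28.3 in het-labelled livers (log2 difference 1.74 ± 0.20, edgeR adjusted p = 0.0208). Its call ended without library 5 or 6 (edgeR adjusted p up to 0.0759). The row of beta haemoglobin stood at 179 ± 36.6 CPM in wild-type and 81.5 ± 6.59 in het-labelled livers (log2 difference -1.13 ± 0.18, edgeR adjusted p = 0.0459). Blood transcripts were lower in the same libraries as the lipid-droplet genes. Alas2 was lower in het-labelled livers on chow too, at 118.8 and 119.6 CPM in wild-type and 72.1 and 63.8 in het-labelled libraries. The Alas2 difference is thus not particular to the HFD libraries. In contrast, the median log2 difference of the 3 tested blood genes was 0.04 on chow and -1.10 on HFD. Kupffer markers had a median of 0.48 (camera adjusted p = 1.47e-05, and adjusted p = 0.499 with an estimated correlation), which was 0.015 without library 7 and 0.768 without library 8. Immediate early genes had one of 0.72 (camera adjusted p = 4.24e-08, and adjusted p = 0.262 with an estimated correlation), which was 0.20 without library 8 and 0.998 without library 6. Of 29 cell cycle genes, 0 were higher and 1 lower (0 and 3 adjusted over the list alone). The camera adjusted p was 0.000165, and adjusted p = 0.444 with an estimated correlation. With a mean of at least 5 CPM the list lost its call (adjusted p = 0.0648), its median going from -0.448 to -0.0608. The called one was Cdkn1a, a cyclin-dependent kinase inhibitor, at 15.2 ± 5.69 CPM in wild-type and 3.39 ± 0.669 in het-labelled livers (log2 difference -2.15 ± 0.27, edgeR adjusted p = 0.0244). The call of Cdkn1a ended without library 1, 2 or 8 and that of beta haemoglobin without any 1 of libraries 1, 2, 5, 6, 7 and 8, and also with upper-quartile scaling or with a mean CPM of at least 5 (edgeR adjusted p up to 0.23).

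On HFD, 56 genes differed between genotypes, 12 higher and 44 lower in het-labelled livers (edgeR, adjusted p under 0.05). The count was 12, 12, 13, 18 and 15 without libraries 1, 2, 5, 6 and 8, 100, 99 and 177 without libraries 3, 4 and 7, and 241 with DESeq2. Camera passed 15 of 27 lists, and with an estimated correlation 0 passed, the smallest adjusted p being 0.195. Of the 44 lower genes, 22 had risen on HFD in wild-type livers, against 1.04 for independent lists. Both comparisons use libraries 5 and 6, so part of that excess may come from those libraries. The covariance of their log2 changes across genes was -0.0386, against -0.0167 simulated with no effect, while the correlation was weaker than simulated (r = -0.389 against -0.491) and 35.75% of genes had the same sign against 33.5%.

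On chow, het-labelled livers were compared with wild-type livers to find genotype differences without the high fat diet. Kupffer cell markers and interferon-responsive genes were higher in het-labelled livers. Siglec1, a macrophage lectin induced by interferon, stood at 3.02 ± 1.07 CPM in wild-type and 13.3 ± 1.46 in het-labelled livers (log2 difference 2.14 ± 0.24, edgeR adjusted p = 0.0247). C1qa, a complement component made by macrophages, stood at 17.7 ± 1.10 CPM in wild-type and 40.00 ± 1.45 in het-labelled livers (log2 difference 1.18 ± 0.14, edgeR adjusted p = 0.0262). Clec4f stood at 50.6 ± 4.21 CPM in wild-type and 117 ± 9.79 in het-labelled livers (log2 difference 1.20 ± 0.17, edgeR adjusted p = 0.0407). Of 19 Kupffer cell and macrophage markers, 7 were higher and 0 lower (18 and 0 adjusted over the list alone). Tested with camera, the list had adjusted p = 3.41e-39, and adjusted p = 0.213 with an estimated correlation. Its median log2 difference was 1.28. Het-labelled chow libraries 3 and 4 also enter the fall of these markers with the diet, so the rise and that fall are not independent results. Oas2, an antiviral oligoadenylate synthetase, stood at 3.002 ± 0.592 CPM in wild-type and 9.19 ± 0.865 in het-labelled livers (log2 difference 1.61 ± 0.18, edgeR adjusted p = 0.0247). Ifit1 stood at 5.94 ± 1.19 CPM in wild-type and 14.2 ± 2.14 in het-labelled livers (log2 difference 1.25 ± 0.18, edgeR adjusted p = 0.0407). Of 30 genes of the interferon response, 4 were higher and 0 lower (19 and 0 adjusted over the list alone). Camera gave this list an adjusted p of 7.70e-18, and adjusted p = 0.287 with an estimated correlation. Endothelial and stellate marker lists did not pass, with medians of 0.12 and 0.07. Lymphocyte markers had a median of 0.48 with 0 genes called (camera adjusted p = 0.00945, and adjusted p = 0.287 with an estimated correlation). Of 25 inflammation genes, 0 were higher and 0 lower (6 and 1 adjusted over the list alone). With camera the list had adjusted p = 0.00018, and adjusted p = 0.287 with an estimated correlation. With a mean of at least 5 CPM the inflammation list's median of 0.670 became -0.133 and its call ended (adjusted p = 0.776). The calls of Siglec1, C1qa, Clec4f, Oas2 and Ifit1 ended without any 1 of libraries 1, 2, 3 and 6, and those of Clec4f and Ifit1 also without library 5 or with a mean CPM of at least 5, with edgeR adjusted p up to 0.31. The Kupffer count was 0 without any of those 4, 1 without library 5, 12 without library 4 and 14 without library 7 or 8, and the interferon count was 0 without any of those 4, 1 without library 5 and 2 without library 4.

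**Figure D4:**
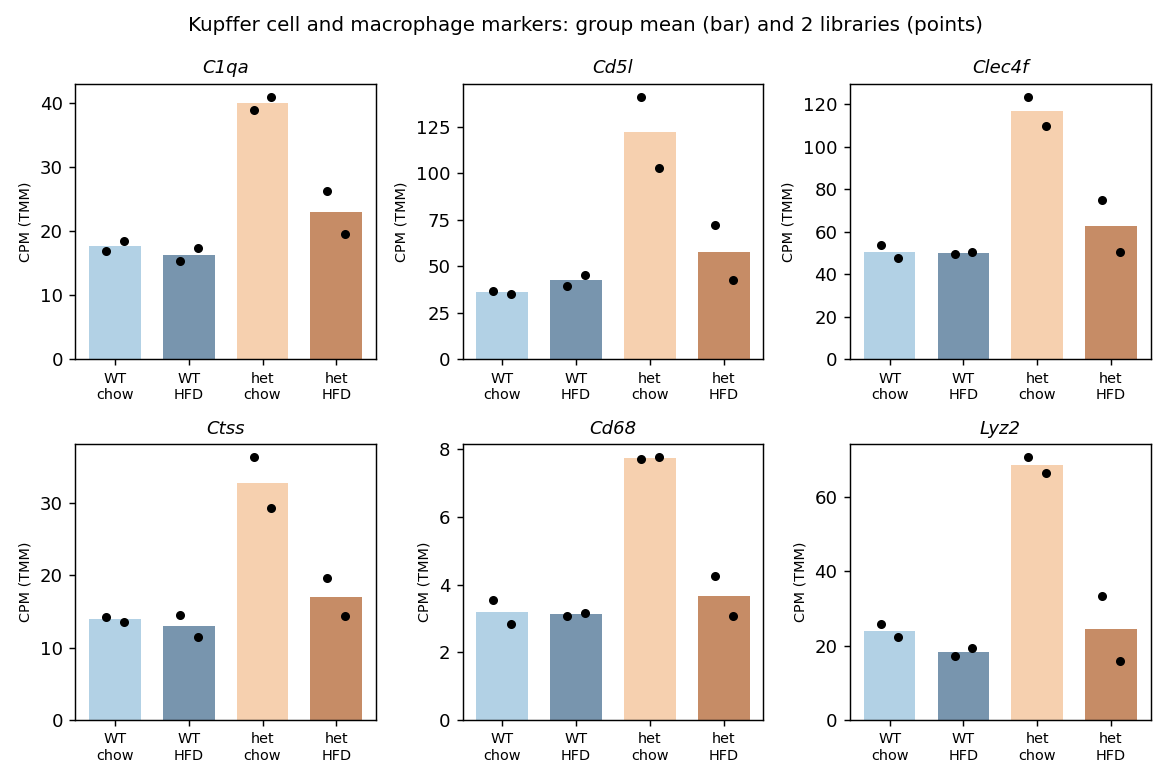
CPM (linear axes from 0, scaled with TMM factors) of the Kupffer cell and macrophage markers C1qa, Cd5l, Clec4f, Ctss, Cd68 and Lyz2 in the 4 groups, with bars for group means and points for the 2 libraries of each group. Clec4f averaged 117 CPM in the het-labelled chow libraries and 50.6, 49.9 and 62.6 in wild-type chow, wild-type HFD and het-labelled HFD.

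Single genes of other kinds differed on chow as well. Lower in het-labelled livers was Aqp4, at 3.27 ± 0.619 CPM in wild-type and 0.519 ± 0.132 in het-labelled livers (log2 difference -2.64 ± 0.28, edgeR adjusted p = 0.0222). Asns stood at 6.63 ± 1.28 CPM in wild-type and 1.70 ± 0.196 in het-labelled livers (log2 difference -1.96 ± 0.24, edgeR adjusted p = 0.0262). Adora1, the A1 adenosine receptor, stood at 20.6 ± 1.99 CPM in wild-type and 7.02 ± 0.693 in het-labelled livers (log2 difference -1.55 ± 0.20, edgeR adjusted p = 0.0322). Fitm1 was the only lipid-droplet gene called, at 33.1 ± 4.97 CPM in wild-type and 9.25 ± 1.25 in het-labelled livers (log2 difference -1.84 ± 0.31, edgeR adjusted p = 0.0482). The list had 0 higher and 5 lower members adjusted over the list alone, and a median of -0.22 (-0.23 without Cidea). Its camera test gave adjusted p = 0.000318, and adjusted p = 0.337 with an estimated correlation. Cyp2b9, a cytochrome P450 more abundant in females, was higher, at 0.557 ± 0.460 CPM in wild-type and 33.8 ± 1.24 in het-labelled livers (log2 difference 5.93 ± 0.98, edgeR adjusted p = 0.0482). Mettl7a3 was read in 6 and 0 counts in wild-type and 140 and 143 in het-labelled libraries (edgeR adjusted p = 0.00793). Its call stood under all alternatives run for it. These left out the fit to the compared groups alone and the filter at a mean of 5 CPM, which Mettl7a3 did not reach. The calls of Aqp4 and Asns ended without any 1 of libraries 1, 2, 3 and 6, and those of Adora1, Fitm1 and Cyp2b9 also without library 5 or with a mean CPM of at least 5 (Fitm1 also without library 4), with edgeR adjusted p up to 0.355. Ifit1, Fitm1 and Cyp2b9 were not called with limma-voom. Clock genes were lower as a list, with 0 genes called (median -0.59, camera adjusted p = 1.34e-05, and adjusted p = 0.287 with an estimated correlation). For xenobiotic metabolism the median was -0.22, the mean 0.11 and the tested direction down (camera adjusted p = 0.00120, and adjusted p = 0.337 with an estimated correlation), and without 1 member that had no reads in wild-type chow libraries the median was -0.23.

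On chow, 65 genes differed between genotypes, 41 higher and 24 lower in het-labelled livers (edgeR, adjusted p under 0.05). The count was 1, 1, 15, 4 and 5 without libraries 1, 2, 5, 6 and 3, and 268, 130 and 133 without libraries 4, 7 and 8. DESeq2 called 227, of which 95 were higher. Camera passed 17 of 27 lists, and 0 passed with an estimated correlation, with a smallest adjusted p of 0.213. Genes called lower on both diets numbered 9 (0.0839 for independent lists) and genes called higher on both numbered 2 (0.0391).

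The series design looks for genes altered by the diet in wild-type livers and less so in mice labelled MLL4 het, and the interaction of genotype and diet tests that difference itself. No gene passed: edgeR called 0 of 12593, with a smallest adjusted p of 0.0963 and 900 genes under an unadjusted p of 0.05. Counts simulated with the same diet effect in both genotypes gave 605 such genes (range 557 to 639) with shared dispersions and 625 (range 567 to 683) with dispersions per genotype. The genes were drawn independently in these simulations, while the correlation estimated between ribosomal protein genes was 0.766. Counts from correlated genes would spread more widely. The observed number lies above both ranges, but that alone does not show an interaction. It moved from 589 without library 1 to 1867 without library 4, and the simulation was not repeated with fewer libraries. DESeq2 called 29 and limma-voom 0. Cyp2b10 and Slc39a4 had the smallest adjusted p, with interaction log2 values of -2.74 ± 0.31 and -1.89 ± 0.22 (edgeR adjusted p = 0.0963 and 0.0963), both having fallen further in het-labelled livers. Cidec had -2.13 ± 0.70 (edgeR adjusted p = 0.628) and Cyp7a1 1.56 ± 0.28 (edgeR adjusted p = 0.367). Siglec1, higher in het-labelled livers on chow and not on HFD, had -2.01 ± 0.35 (edgeR adjusted p = 0.360). Without library 7 the number of called genes was 14, without library 3 or 4 it was 2, and without library 6 it was 1.

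Of the 578 genes called in wild-type livers, 562 had the same sign in het-labelled livers and 366 were not called there. Counts simulated with the same diet effect in both genotypes gave 421 such genes (range 379 to 479 over 20 draws) with shared dispersions and 298 (range 260 to 346) with dispersions per genotype, though they made more calls overall than observed (938 and 841 against 578 in wild-type). As a share of wild-type calls, 63.3% were not called in het-labelled livers, against 44.9% simulated with shared dispersions and 35.4% with dispersions per genotype. Of het-labelled calls, 44.2% were not called in wild-type livers, against 42.6% and 52.9% simulated. These shares depend on the number of calls, which differed from the simulated one, and the genes were again simulated independently of each other. The 366 became 42, 66, 79 and 84 without libraries 1, 2, 5 and 6, and 720 and 776 without libraries 3 and 4. Genes picked for a log2 change of at least 1 between 1 wild-type chow and 1 wild-type HFD library changed by a median of 1.18 in the remaining wild-type pair and 0.87 in het-labelled pairs, a ratio of 0.741 (range 0.687 to 0.791 over 4 selections). When het-labelled libraries made the selection, the remaining het-labelled pair gave 0.695 and wild-type pairs 0.655, a ratio of 0.935 (range 0.442 to 1.53). All selections reuse the same libraries, so these ranges do not measure the uncertainty of the ratios.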

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

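Tests of technical explanations in this part were chosen after the results were seen, while the list tests of the interaction were planned. With 2 libraries in each group, a difference between them does not show which of them is unusual. For 15 of 27 gene lists, the diet response differed between the genotypes by camera with the preset correlation, and with an estimated correlation none passed, the smallest adjusted p being 0.311. Negative values below mean a log2 change from chow to HFD that was lower in het-labelled than in wild-type livers, be it a smaller rise or a larger fall, given as the median log2 interaction of the list and the camera adjusted p. Kupffer cell and macrophage markers had -0.873 (4.28e-15), cell cycle genes -0.677 (3.16e-07), interferon response genes -0.534 (8.51e-07) and liver genes more abundant in females -0.351 (1.36e-06). De novo lipogenesis had -0.332 (0.0112), inflammation -0.311 (0.0268), PPARG lipid-droplet genes -0.311 (0.000625, and a median of -0.26 without Cidea) and PPARA fatty-acid oxidation -0.197 (6.13e-06). Positive medians were found for nuclear genes of oxidative phosphorylation at 0.0733 (0.0494), bile acid genes at 0.136 (0.00212), hepatocyte genes at 0.161 (0.000114), ribosomal proteins at 0.255 (3.50e-14), liver genes more abundant in males at 0.360 (1.70e-07), clock genes at 0.507 (9.53e-05) and immediate early genes at 0.810 (6.81e-12). Leaving out each library in turn gave ranges of these medians of -1.26 to -0.634 for Kupffer markers, -0.853 to -0.485 for cell cycle, -0.600 to -0.122 for interferon response, -1.77 to -0.172 for the female list, -0.549 to -0.0147 for lipogenesis, -0.611 to -0.0895 for inflammation, -0.444 to -0.205 for lipid-droplet and -0.290 to -0.0759 for PPARA genes. The others spanned -0.00900 to 0.164 (oxidative phosphorylation), 0.0282 to 0.217 (bile acid), 0.0534 to 0.234 (hepatocyte), 0.176 to 0.340 (ribosomal), 0.289 to 0.438 (male list), 0.00228 to 0.703 (clock) and 0.485 to 1.22 (immediate early genes, lowest without library 8). The call of the lipid-droplet list ended without library 8 (adjusted p = 0.107), that of the clock list without library 7 (0.0505), those of lipogenesis, bile acid, inflammation and oxidative phosphorylation genes without 2 or more single libraries, and those of the cell cycle, inflammation and oxidative phosphorylation lists with a mean of at least 5 CPM (0.0568, 0.609 and 0.0926, with a cell cycle median of -0.207).

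Lipid-droplet genes were lower in het-labelled than in wild-type livers on HFD, with a median log2 difference of -0.48. Fat tissue caught in the wild-type HFD samples was tested with Adipoq, Retn, Lep and Plin1, abundant in fat cells and held by no other list, which together gained 0.286% of the 18.2 CPM that Cidec gained from chow to HFD. This argues against fat tissue as the source, although Cfd and Fabp4, also made by fat cells, gained 16.4 and 2.05 CPM, and the adipocyte list as a whole, which holds Cidea, was lower too in het-labelled livers on HFD (median -0.46, camera adjusted p = 0.000179, and 0.195 with an estimated correlation). No single HFD library set the size of the difference, since the median nearest 0 without 1 of them was -0.41, though the number of lower genes called fell to 3 without library 6, 1 without library 5 or 8 and 0 without chow library 1 or 2. An effect of the genotype stays open as a hypothesis, as do unrecorded differences between these 4 HFD libraries, in which the merged row of the blood transcripts Hbb-b1 and Hbb-b2 differed in the same direction (log2 fold change -1.13 ± 0.18, edgeR adjusted p = 0.0459).

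Kupffer cell markers were higher in het-labelled than in wild-type livers on chow, with a median log2 difference of 1.28. Their fall with the diet in het-labelled livers and their interaction use the same het-labelled chow libraries and are not separate findings. In wild-type livers their median change with the diet was -0.18. A lower share of hepatocytes would raise the markers of other cell types alike, but the larger of the endothelial and stellate medians was 0.117, below the 1.14 to 1.35 that Kupffer markers spanned without each chow library, and the lymphocyte median was 0.48 (camera adjusted p = 0.00945, and 0.287 with an estimated correlation). Without each chow library the endothelial median spanned -0.229 to 0.284 and the stellate median -0.0217 to 0.120, also below the Kupffer range. Hepatocyte genes had a median of -0.143 (camera adjusted p = 0.00945, a call that ended without library 3 and with an estimated correlation, at 0.562), so a smaller shift in hepatocyte share beside the rise of Kupffer markers stays open. No single chow library set the size, since the median nearest 0 without 1 of them was 1.14, though the number of markers called fell from 7 to 0 without library 1, 2 or 3, and also without HFD library 6. Neutrophil markers, with 3 tested members and so no list test, had a median of 1.05 on chow. Of these, 0 were called and 2 were higher adjusted over the list alone. Whether the rise was confined to Kupffer cells was not tested. A larger number of Kupffer cells and a change in their state, with the genotype as a possible source, stay open as hypotheses, and the design cannot separate them from unrecorded differences between the 4 chow libraries.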

How the results depend on the processing

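The p-values rest on 2 libraries per group, and the counts of called genes moved widely when a library was left out. Where a group was left with 1 library, that library was assumed to vary like the other groups. No paired analysis was possible because the library numbers all differ and none is shared between groups. Leaving out each library in turn gave 98 to 896 called genes for the diet in wild-type livers (578 with all libraries), 144 to 293 for the diet in het-labelled livers (380), 12 to 177 for the genotype on HFD (56), 1 to 268 for the genotype on chow (65) and 0 to 14 for the interaction (0). Genes called for the diet in wild-type and not in het-labelled livers, 366 with all libraries, numbered 42 to 776, an alternative added after seeing the data. The numbers for these comparisons at an adjusted p under 0.10 were 1001, 722, 211, 285 and 2. With no filter they were 680 for the diet in het-labelled livers, 258 for the genotype on HFD, 314 on chow and 8 for the interaction, and with a mean of at least 5 CPM they were 252, 31 and 12 for the first 3 of these. DESeq2 called 241 for the genotype on HFD, 227 on chow and 29 for the interaction, and limma-voom called 24 on chow. Fits to the compared groups alone called 1351 for the diet in wild-type livers, 105 in het-labelled livers and 26 for the genotype on HFD. More genes tested, fewer genes tested and fewer libraries are part of these settings, and beyond that the cause was not tested. Fits to the compared groups alone also take the spread from those groups. The coefficient of variation was 7.59% and 8.70% in wild-type and 13.8% and 13.6% in het-labelled groups, while the main fit shares an estimate between them. Counts of diet calls in both genotypes are therefore not directly comparable. Both other scalings kept all 5 counts within 1.5 times, from 582 and 594 for the diet in wild-type livers to 56 and 78 for the genotype on chow. With an estimated correlation, 2, 1, 0, 0 and 0 lists passed camera, in place of 15, 14, 15, 17 and 15, and fry passed 11, 7, 3, 2 and 0 (19, 22, 12, 13 and 3 in its mixed form). For the genotype on chow, fry passed the H3K4 methyltransferase and adipocyte lists (adjusted p = 0.0423 and 0.0469). The Kupffer and interferon lists did not pass it there (fry adjusted p = 0.0682 and 0.0899). On HFD it passed the H3K4 methyltransferase, adipocyte and lipid-droplet lists (adjusted p = 0.0308, 0.0308 and 0.0459). Among list results that passed with all libraries or in the alternative, test direction turned for 5, where the cause was not tested. Medians of other lists changed sign too, such as that of immediate early genes on chow, from -0.127 to 0.173 without library 3. On chow the inflammation list had a median difference of -0.133 with a mean of at least 5 CPM, and the endothelial list spanned -0.229 (without library 3) to 0.284. The list of cholesterol synthesis on HFD spanned -0.397 to 0.133 (without library 5), with 0.0335 without library 7. The list of PPARA fatty-acid oxidation in the diet comparison of het-labelled livers spanned 0.00714 to 0.188, with 0.0389 and a downward test without library 3, and the unfolded protein response in the interaction spanned -0.197 (without library 4) to 0.124. Of 212 results for named genes that were called, 74 passed in every alternative run, up to 14 each, and 0 reversed. For genes with a lower mean, those alternatives did not include the filter at a mean of 5 CPM. They did not include the fits to the compared groups alone either. Such fits also called 17 of the 56 genes called for the genotype on HFD and 37 of the 65 on chow. The ratio of held-out diet effects was 0.741 and lay between 0.734 and 0.777 in its alternatives. Simulated genes called in het-labelled livers alone numbered 384 with shared and 609 with genotype dispersions, against 168 observed. Depth limits low genes, since 3 counts correspond to 0.158 CPM in the deepest library and 0.212 CPM in the shallowest.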

Other observations

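Tests of explanations for the Mettl7a rows in this part were chosen after the result was seen. Lists of genes whose liver levels differ between the sexes were lower on HFD in 3 of 4 tests, none of which passed with an estimated correlation. All libraries held RNA of the Y-linked genes Ddx3y, at 60.1 to 78.3 CPM, and Kdm5d, at 18.6 to 20.6 CPM, with 1 to 9 counts of Xist. Of 22 genes more abundant in male liver, 0 rose and 7 fell (0 and 9 adjusted over the list alone) in wild-type livers, with a median of -0.28 (camera adjusted p = 1.61e-11, and adjusted p = 0.0849 with an estimated correlation). The median was -0.451 without library 6. In het-labelled livers 0 rose and 3 fell (1 and 7 adjusted over the list alone), with a median of -0.08, and the list did not pass (camera adjusted p = 0.0506), but did with a mean of at least 5 CPM (0.0328). In wild-type livers Selenbp2, a selenium-binding protein, fell from 1319 ± 108 to 345 ± 77.2 CPM (log2 fold change -1.93 ± 0.23, edgeR adjusted p = 0.00361). Susd4, a complement regulator, fell from 40.6 ± 0.860 to 16.3 ± 1.14 CPM (log2 fold change -1.31 ± 0.12, edgeR adjusted p = 0.00148) in wild-type livers. Of 19 genes more abundant in female liver, 0 rose and 3 fell (0 and 8 adjusted over the list alone) in het-labelled livers (1 fell without library 1 or 2 and 5 without library 7), with a median of -1.08, and -0.63 without library 4 (camera adjusted p = 1.27e-12, and adjusted p = 0.0857 with an estimated correlation). In wild-type livers 1 rose and 4 fell (2 and 5 adjusted over the list alone), with a median of -0.45 that was -0.59 without a member lacking reads in a group (camera adjusted p = 0.00178, and adjusted p = 0.329 with an estimated correlation), and this call ended without library 6 (adjusted p = 0.118). The number of fallen genes there was 1 without library 1, 2 or 6 and 2 without library 5, and that of risen genes 0 without library 1, 2 or 5 and 2 without library 7 or 8. In the het-labelled male list, 1 fell without library 3, 4 or 7 and 2 fell without library 1 or 2. Cyp3a44, a cytochrome P450, fell from 18.7 ± 1.25 to 5.59 ± 1.22 CPM (log2 fold change -1.73 ± 0.31, edgeR adjusted p = 0.0187) in wild-type livers and from 15.3 ± 2.35 to 4.44 ± 2.75 CPM (log2 fold change -1.74 ± 0.33, edgeR adjusted p = 0.0306) in het-labelled livers. Its calls ended without any 1 of libraries 1, 2, 5 and 6 in wild-type livers (edgeR adjusted p up to 0.129) and without any 1 of libraries 1, 2, 3 and 4 in het-labelled livers (up to 0.0949).

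Ribosomal protein genes were slightly lower on HFD in wild-type livers. Of 59, 0 rose and 5 fell (0 and 52 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 1.14e-18, and adjusted p = 0.347 with an estimated correlation). The number called was 0 without library 1, 2, 5 or 6, and 23 and 26 without libraries 3 and 4. In het-labelled livers the median was -0.07 and 0 genes were called. Adipocyte markers were lower in het-labelled livers on both diets, with medians of -0.46 on HFD (camera adjusted p = 0.000179, and adjusted p = 0.195 with an estimated correlation) and -0.33 on chow (camera adjusted p = 0.000315, and adjusted p = 0.213 with an estimated correlation), the latter -0.49 without Cidea, which lacked reads in a group, over 7 genes that include Cidea and the liver genes Pck1 and Car3. Adrb3, the beta-3 adrenergic receptor, stood at 12.3 ± 0.472 CPM in wild-type and 3.59 ± 1.17 in het-labelled livers (log2 difference -1.77 ± 0.25, edgeR adjusted p = 0.0407) on chow, a call that ended without library 1, 2, 3 or 6 and with a mean of at least 5 CPM (edgeR adjusted p up to 0.277). Fabp2, a fatty acid binding protein best known from gut, rose from 46.6 ± 0.549 to 179 ± 4.98 CPM (log2 fold change 1.95 ± 0.12, edgeR adjusted p = 0.00017) in wild-type livers and from 34.3 ± 1.77 to 145 ± 23.6 CPM (log2 fold change 2.08 ± 0.12, edgeR adjusted p = 9.35e-05) in het-labelled livers. Tap1, a peptide transporter of antigen presentation, rose by a log2 fold change of 0.70 ± 0.14 in wild-type livers (edgeR adjusted p = 0.0246), as the 1 called gene of the interferon response list there, whose median was 0.25 (camera adjusted p = 0.0227, and adjusted p = 0.602 with an estimated correlation). The Tap1 call ended without library 1, 2 or 5 (edgeR adjusted p up to 0.237), and the list's median was 0.0886 without library 1. Gadd45a, induced by growth arrest and DNA damage, and Rrm2, a subunit of ribonucleotide reductase, rose in wild-type livers with log2 fold changes of 1.72 ± 0.37 and 1.12 ± 0.24 (edgeR adjusted p = 0.0345 and 0.0375). Both calls were lost when library 1, 2, 5 or 6 was left out, and that of Gadd45a also with limma-voom (adjusted p up to 0.293). The cell cycle list to which they belong had a median of 0.38 (camera adjusted p = 0.00110, and adjusted p = 0.347 with an estimated correlation), and -0.0352 with a mean of at least 5 CPM, which ended its call.

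Rows of Mettl7a3 and Mettl7a2, neighbours of Kmt2d in the table of gene order, were higher in het-labelled livers on both diets, and reads passing between the near-identical copies would lower Mettl7a1 by what the others gained. A first test over both diets together decided nothing, and the diets were then tested apart. On chow Mettl7a1 fell by 35.6 CPM (SE 10.8) against a gain of 22.3 in the others, which would be enough. The gain minus the fall was -13.2 CPM there, with an SE of 12.1. The edgeR test did not call the fall of Mettl7a1 on chow (adjusted p = 0.368). On HFD it fell by -0.400 CPM, that is, it did not fall (SE 10.3), while the others gained 22.8 CPM, but the gain minus the fall of 23.2 CPM has an SE of 11.97, so these values do not decide between such reads and a true gain on HFD. A segment of another strain around Kmt2d may also be the cause and stays open, since, with the Mettl7a rows themselves not counted, 4 of the 100 tested genes nearest to Kmt2d (Arsa, Fkbp11, Smarcd1 and Gpd1, chosen after their values were seen) differed with the same sign and an unadjusted p under 0.05 on both diets, where windows of that size across the genome had a median of 4 and a 95th percentile of 8.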
